A study of Homo sapiens with 6 samples.

How the data were processed

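RNA sequencing data of 6 libraries from HTR-8/SVneo cells were used, 3 labelled control and 3 labelled FABP4 si267. Per the labels' protocols, RNA was isolated with TRIzol, enriched for polyadenylated transcripts, and made into strand-specific libraries by the dUTP method for paired-end Illumina sequencing. The genome build was GRCh38 (hg38), per the submitters' processing notes. The aligner, the counting tool, the annotation and whether counting used strand are not given in the sources used here. Nothing in the labels says that the replicates of a group were grown as separate cultures, so p-values measure only the spread between these samples, which may be technical.

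The deposited table held 1 value per gene and library for 63086 Ensembl gene identifiers, in whole numbers, and was treated as estimated counts. The values were not a plain tally of fragments. Low values piled up at multiples of 4, with values at the step of 4 being 1.37 times as frequent as their neighbours and those at steps of 2, 3, 5 and 6 between 0.863 and 1.04 times. The variance between replicates of genes with a mean count between 1 and 10 had a median of 3.29 times the mean in control and 3.24 times the mean in FABP4 si267 libraries. A fragment was therefore taken to be worth about 4 counts, so that total counts of 62600904 to 72469030 correspond to about 15650200 to 18117300 fragments. Count-based intervals and floors cover counting error only, and the floor for a count of 0 was set at 3 fragments, or 12 counts per library. As the values were already whole, no rounding was needed for the test. All columns belonged to a labelled sample.

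Of the identifiers, 62541 were found in the table of gene names and 58072 in GENCODE release 29, from which coordinates were taken. In all 6 libraries 30158 identifiers had a count of 0, among them 3634 of the 19831 protein-coding genes of GENCODE 29 (18.3%). Where a symbol belonged to more than 1 identifier, the one with the highest total over all libraries stood for it in the gene lists. Genes that overlap others on the same strand, readthrough genes and pseudogenes are uncertain, because the way reads were divided among them is not given.

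Differential expression was tested with edgeR 4.0.16 in R 4.3.3, using the quasi-likelihood test on the deposited counts with TMM normalisation, genes kept by filterByExpr and no covariate besides the group. CPM (counts-per-million) values are relative to the TMM-scaled total of the genes kept, and the TMM factors ranged from 0.973 to 1.02. P-values were adjusted by the Benjamini-Hochberg method over the 19513 genes tested, with a threshold of 0.05. Confidence intervals are at the 95% level. Gene lists were tested with camera in limma 3.58.1, two-sided, with a preset inter-gene correlation of 0.01 on log2 CPM (prior count 2), adjusted over 27 lists of at least 5 tested members each. The lists covered lipid metabolism, mitochondria, redox and stress responses, the cell cycle, interferon and inflammation, trophoblast identity and markers of other cell types. One member, of the adipocyte list, was not found in the table. Camera with a correlation estimated per list and fry were run beside it. With 3 samples against 3, an exact permutation test of a single gene cannot give a two-sided p under 0.1.

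The design, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule named FABP4, the 10 genes with the largest positive and the 10 with the largest negative log2 fold change among those that passed the threshold with a mean of at least 5 CPM, non-overlapping groups and a gene symbol, and up to 4 passing members of each list. Where no member passed, up to 2 members with the highest mean CPM were named with their values. No gene passed the threshold, so the named genes are FABP4 and the most abundant list members. Other genes were chosen after their values were seen.

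The titles and descriptions number the replicates 1 to 3 in both groups, but do not state a shared day or batch. Whether the numbers pair the samples was checked from the correlation across genes of same-numbered samples' deviations from their group means, before the calls of the 2 fits were compared. Over all tested genes it was 0.0961, 0.0821 and 0.0434 for numbers 1, 2 and 3, each under 0.1. Over genes with a mean of at least 5 CPM it was 0.299, 0.295 and 0.168. It was negative for every pair of different numbers, but deviations cancel within a group, so these signs largely follow and add no separate support. The numbers were treated as pairing the samples on the second set of values, because low counts carry mostly sampling noise. That choice was made with both sets in view. The main fit had been fixed without a block, so its calls, SEs and intervals leave out the pairing. The fit with the replicate number as a block is given where it changed a call.

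The test was checked on simulated counts for this comparison, drawn from the measured means and library sizes, with 200 genes changed among 19017 genes tested. It recovered 15 of 67 genes changed 1.5-fold (22.4%), 55 of 67 changed 2-fold (82.1%) and 66 of 66 changed 4-fold. Of its 153 calls, 17 were unchanged genes, a larger share than the adjusted p threshold of 0.05. All changed genes were drawn from those with a mean of at least 5 CPM. Recovery therefore does not show how many changes are found among genes with a mean under 5 CPM. All 10 simulated lists of 25 genes shifted by 0.3 on the log2 scale were recovered, and 0 of 10 unshifted lists were called. Each gene was drawn independently, so this check does not cover lists whose genes vary together. The simulated shift was also larger than the medians of the lists called in the measured data.

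Alternatives covered RLE size factors, library size only, DESeq2 1.42.0, limma-voom, no filter and a stricter filter on low counts (at least 1 CPM in at least 3 libraries and a mean of at least 5 CPM), the replicate block, each library left out in turn, a 2-fold minimum and an adjusted p under 0.01. Counts divided by 4 and rounded were added after the data were seen. Tables were handled with pandas 2.3.3, Fisher's exact tests were run with scipy 1.17.1, trends were fitted with statsmodels 0.14.6 and figures drawn with matplotlib 3.10.9. Samples of placental tissue and an inhibitor of FABP4 that the series mentions were not analysed here.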

Results

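Gene expression was measured by RNA sequencing in HTR-8/SVneo cells, an immortalised line derived from first-trimester human extravillous trophoblast, the placental cells that invade the uterine wall. The 6 libraries formed 2 groups of 3 replicates. One group was labelled control with a wild-type genotype, and the other had received si267, a small interfering RNA against FABP4. FABP4 encodes a fatty acid binding protein best known from adipocytes and macrophages. The labels do not say whether the control cells received a non-targeting siRNA. Total counts were 62600904, 64899873 and 67745041 in control replicates 1, 2 and 3, and 72469030, 64420665 and 68376930 in FABP4 si267 replicates 1, 2 and 3. Between 25363 and 26063 genes had a count above 0 in a library. The study asked whether FABP4 acts on lipid metabolism and mitochondrial oxidative stress in trophoblasts in the context of preeclampsia, a hypertensive disorder of pregnancy. The comparison of cells given si267 with control cells bears on that question at the level of RNA.

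The siRNA target was examined first. FABP4 (ENSG00000170323, chromosome 8, 81478419 to 81483263 on the minus strand in GRCh38) had 0 counts in all 3 control and all 3 FABP4 si267 libraries. A count of 0 allows up to 12 counts per library, which corresponded to between 0.166 and 0.192 counts-per-million units (CPM) of the raw total, without the TMM scaling of the other CPM values. This floor takes 3 fragments at about 4 counts each and covers counting error only. The deposited table thus lists the target at 0 in both groups, and the counting tool is not given in the sources used here. No fold change was computed, a permutation test of 6 equal values carries no information, and the level of FABP4 could not check the group labels. Of the related fatty acid binding protein genes, FABP1, FABP7, FABP12 and PMP2 were also at 0 in all 6 libraries. FABP5, the neighbouring epidermal-type member (ENSG00000164687, chromosome 8, 81280363 to 81284777), was measured at 1.45 ± 0.34 CPM in control and 1.67 ± 0.65 CPM in FABP4 si267 libraries (mean ± SD, n = 3 each), a difference smaller than the spread between replicates. FABP6, the ileal-type member, stood at 1.06 ± 0.34 and 0.569 ± 0.034 CPM, a log2 fold change of −0.89 (SE 0.36) with the FABP4 si267 libraries all lower and an adjusted p of 1.00, and was chosen after its values were seen. PPARG, a nuclear receptor that regulates FABP4 in adipocytes, stood at 0.626 ± 0.207 and 0.617 ± 0.161 CPM. LPL, the lipoprotein lipase gene, was at 0 in all 6 libraries.

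Across the transcriptome no gene was called as changed between FABP4 si267 and control cells. Of 19513 genes tested with edgeR's quasi-likelihood test, 0 rose and 0 fell at a Benjamini-Hochberg adjusted p under 0.05. At an unadjusted p under 0.05 there were 565 genes (2.90% of those tested), a smaller share than the 0.05 that chance gives on average. Of these genes 277 were higher and 288 lower in the FABP4 si267 libraries. The groups did not overlap for 1591 genes (8.15%), where chance gives 10% for 3 against 3 exchangeable libraries and less if same-numbered libraries vary together. The smallest adjusted p was 0.302, for ENSG00000255439, a low-abundance annotated protein-coding gene on chromosome 16 (31083439 to 31094956), at 1.11 ± 0.18 CPM in control and 4.54 ± 1.79 CPM in FABP4 si267 libraries. The next was 0.855, for IP6K3, an inositol hexakisphosphate kinase gene on chromosome 6 (33721670 to 33746905), with 3.65 ± 0.30 against 7.66 ± 0.82 CPM and a log2 fold change of 1.07 (SE 0.19). ORAI1, the pore subunit of a plasma membrane calcium channel, measured 105.6 ± 3.2 CPM in control and 70.0 ± 5.7 CPM in FABP4 si267 libraries, a log2 fold change of −0.59 (SE 0.12) with an adjusted p of 1.00. These 3 genes were chosen after their values were seen. DESeq2 called 6 genes, among them these 3, and limma-voom called 0.

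Most changes were bounded closely. Among the 11665 genes with a mean of at least 5 CPM the median SE of the log2 fold change was 0.15 in the fit without a block. For 98.6% of them the 95% confidence interval of that fit lay within a 2-fold change in either direction. With the replicate number as a block, 1 gene was called, CD99 under the identifier ENSG00000002586 (log2 fold change −1.27, SE 0.11, adjusted p = 0.00357). CD99 encodes a cell surface glycoprotein, and its counts were divided over 2 identifiers. ENSG00000002586 stood at 112.2 ± 31.2 CPM in control and 47.2 ± 15.4 CPM in FABP4 si267 libraries, and ENSG00000292348 at 139.8 ± 11.7 and 200.2 ± 9.1 CPM. Their sum was 251.99 ± 20.0 CPM in control and 247.37 ± 7.6 CPM in FABP4 si267 libraries. Leaving out 1 library gave 2 calls without control replicate 1, 2 without control replicate 2, 1 without FABP4 si267 replicate 1, 5 without FABP4 si267 replicate 2 and 3 without FABP4 si267 replicate 3. The number of genes at an unadjusted p under 0.05 was 882 without control replicate 3 and 1202 without FABP4 si267 replicate 1.

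The groups overlapped on the first and on the second principal component. Pearson correlations of log2 CPM across genes, which are not independent replicates, averaged 0.976 between control libraries, 0.978 between FABP4 si267 libraries and 0.977 between the groups. The first principal component held 25.2% of the variance and the second 21.8%. On the first, each FABP4 si267 library lay higher than the control of the same number, at −25.1 against −41.0, 59.4 against 5.79 and 11.6 against −10.7 for numbers 1, 2 and 3. FABP4 si267 replicate 2 lay at one end of the first component and control replicate 3 at one end of the second.

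**Figure D1:**
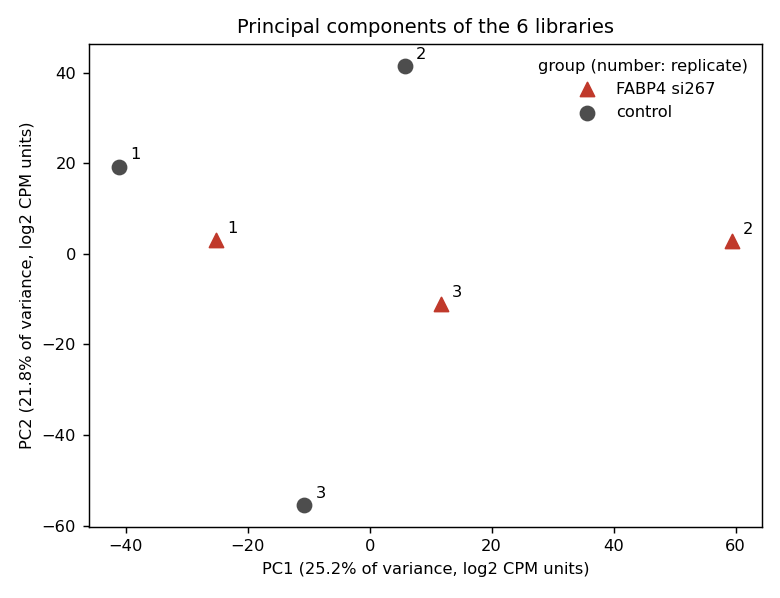
Principal components of log2 CPM over the 19513 tested genes. Each point is 1 library, with the first component (25.2% of the variance) on the horizontal and the second (21.8%) on the vertical axis, circles for control and triangles for FABP4 si267, and numbers giving the replicate. The groups overlap on both axes, each FABP4 si267 library lies to the right of the control of the same number, and FABP4 si267 replicate 2 lies apart at 59.4.

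No shift of lipid handling genes between the groups was called. In none of the 27 gene lists fixed before the data were examined did a member pass the test over all genes, and 0 passed when adjusted over the list alone. Of the fatty acid binding and uptake list, 16 of 26 members were expressed highly enough to be tested, 7 higher and 9 lower in FABP4 si267 cells, with a median log2 fold change of −0.02. CAV1, the caveolin of plasma membrane caveolae, stood at 79.6 ± 10.3 CPM in control and 78.7 ± 9.7 CPM in FABP4 si267 libraries, and ACSL3, an acyl-CoA synthetase of lipid droplets, at 79.1 ± 13.5 and 74.9 ± 4.4 CPM. The fatty acid oxidation list had 17 members higher and 14 lower, with a median of 0.02. ACADVL, the very long chain acyl-CoA dehydrogenase, measured 463 ± 78 and 517 ± 33 CPM (log2 fold change 0.16, 95% confidence interval −0.14 to 0.45). CPT1A, which controls entry of long chain fatty acids into mitochondria, measured 85.6 ± 6.8 and 83.6 ± 4.2 CPM (−0.03, −0.29 to 0.23). In fatty acid synthesis and desaturation, 13 members were higher and 12 lower with a median of 0.03. SCD, the stearoyl-CoA desaturase, gave 458 ± 61 and 493 ± 101 CPM, and TECR, a reductase of fatty acid elongation, gave 529 ± 53 and 477 ± 6.5 CPM. Cholesterol synthesis and uptake had 13 members higher and 11 lower with a median of 0.01. FDPS, the farnesyl diphosphate synthase, stood at 245 ± 28 and 251 ± 20 CPM, and SREBF2, a transcriptional regulator of the pathway, at 208 ± 11 and 207 ± 35 CPM. Triglyceride storage and lipolysis had 11 members higher and 16 lower with a median of −0.03, where the lipid droplet coat gene PLIN3 gave 348 ± 14 and 310 ± 43 CPM and AGPAT1, an acyltransferase of phosphatidic acid synthesis, 269.95 ± 7.1 and 253 ± 8.1 CPM. PPAR targets had 6 members higher and 12 lower with a median of −0.07, and ACADVL and CPT1A were also its most abundant tested members. With 1 library left out the median ranged from −0.08 to 0.02 for binding and uptake, −0.03 to 0.05 for oxidation, −0.06 to 0.08 for synthesis, −0.03 to 0.01 for cholesterol and −0.04 to −0.02 for triglycerides. For PPAR targets it ranged from −0.23 without FABP4 si267 replicate 1 to −0.04 without FABP4 si267 replicate 2. The camera adjusted p over the 27 lists was 0.944 for binding and uptake, 0.750 for oxidation, 0.944 for synthesis, 0.944 for cholesterol, 0.944 for triglycerides and 0.565 for PPAR targets. In the binding, synthesis, cholesterol and triglyceride lists the median and the mean log2 fold change had opposite signs.

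**Figure D2:**
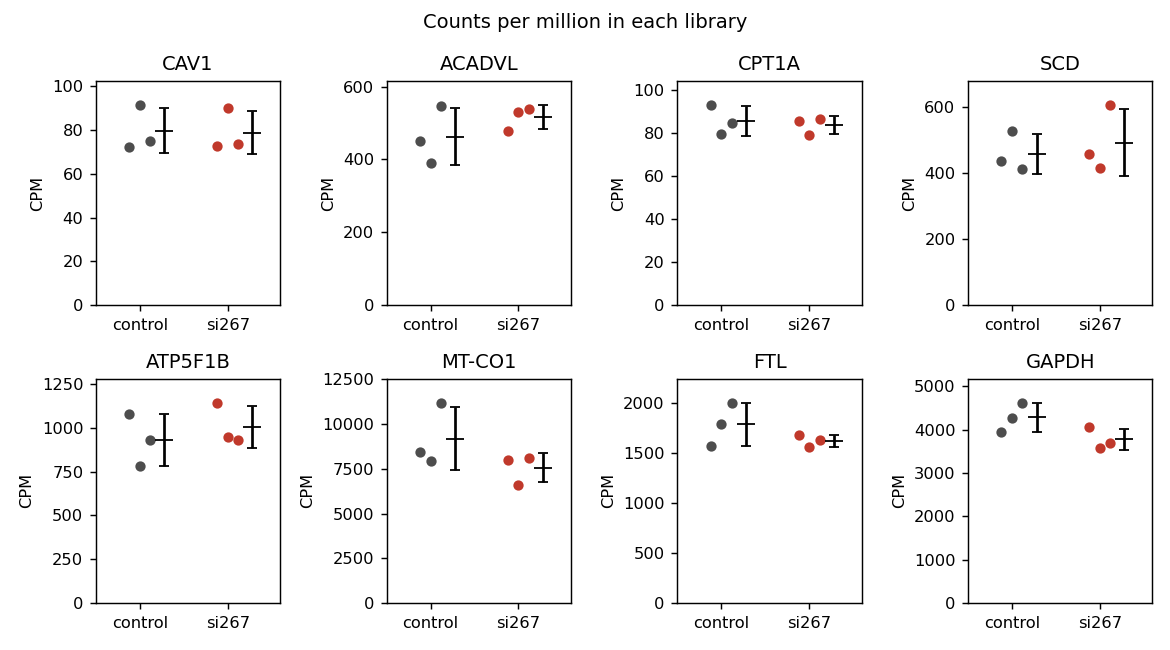
Counts-per-million values (CPM, vertical axes, each starting at 0) of CAV1, ACADVL, CPT1A, SCD, ATP5F1B, MT-CO1, FTL and GAPDH in the 3 control (grey) and 3 FABP4 si267 (red) libraries. Points are single libraries, and the dash with its bar is the mean ± SD. The libraries of the 2 groups overlap for each gene, as for CPT1A with means of 85.6 and 83.6 CPM.

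The respiratory chain was where a gene list test passed with the preset correlation. Of 78 nuclear encoded genes of oxidative phosphorylation, 57 were higher and 21 lower in FABP4 si267 cells, with a median log2 fold change of 0.13 (camera with a preset inter-gene correlation of 0.01, adjusted p = 0.00909). The correlation estimated for this list was 0.206, far above the preset. The call was lost with that estimate (camera adjusted p = 0.950) and with fry (adjusted p = 0.883). Among the most abundant members, ATP5F1B, the catalytic beta subunit of ATP synthase, measured 932 ± 149 CPM in control and 1006 ± 119 CPM in FABP4 si267 libraries (log2 fold change 0.11, SE 0.14), and NDUFB9, a complex I subunit, 440 ± 72 and 493 ± 27 CPM (0.17, SE 0.13). The 13 mitochondrially encoded members pointed the other way, with 1 higher and 12 lower and a median of −0.14. Their camera adjusted p was 0.0589, 0.0369 with the replicate number as a block and 0.950 with the estimated correlation of 0.532. MT-CO1, the catalytic subunit of complex IV, stood at 9188 ± 1758 and 7569 ± 832 CPM, and MT-ND4 of complex I at 7739 ± 454 and 6980 ± 644 CPM. The 13 genes took 4.34, 4.01 and 4.46% of counts in control replicates 1, 2 and 3 and 4.15, 3.55 and 3.82% in FABP4 si267 replicates 1, 2 and 3. The nuclear list also lost its call without control replicate 1 (adjusted p = 0.104, median 0.13), without control replicate 2 (0.142, median 0.07) and without FABP4 si267 replicate 2 (0.675, median 0.05). The mitochondrial list had an adjusted p of 0.267, 0.0129 and 0.359 without control replicate 1, 2 and 3 in turn (medians −0.11, −0.19 and −0.12), and of 0.00887, 0.675 and 0.296 without FABP4 si267 replicate 1, 2 and 3 in turn (medians −0.21, −0.09 and −0.12).

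No shift was called for other mitochondrial and redox gene groups. The list of mitochondrial biogenesis, fusion, fission and mitophagy had 10 members higher and 19 lower with a median of −0.05. Among them MFN2, a mitofusin, gave 166 ± 33 and 172 ± 8.6 CPM, and the mitophagy receptor BNIP3 158 ± 21 and 134 ± 16 CPM in control and FABP4 si267 libraries. The tricarboxylic acid cycle list had 14 higher and 12 lower with a median of 0.01, with DLST, a subunit of the 2-oxoglutarate dehydrogenase complex, at 364 ± 47 and 366 ± 20 CPM and SDHA, the flavoprotein subunit of succinate dehydrogenase, at 328 ± 63 and 322 ± 18 CPM. Targets of NRF2, the transcription factor of the antioxidant response, had 13 higher and 12 lower with a median of 0.01. The ferritin chains FTL and FTH1 stood at 1790 ± 215 against 1622 ± 59 CPM and at 1062 ± 157 against 1085 ± 41 CPM. Genes of reactive oxygen species detoxification had 15 higher and 13 lower with a median of 0.05, with GSTP1, a glutathione transferase, at 689 ± 94 and 625 ± 25 CPM and PRDX1, a peroxiredoxin, at 317 ± 33 and 359 ± 54 CPM. Camera adjusted p-values were 0.565, 0.906, 0.944 and 0.726 for these lists in the order given. Their medians ranged from −0.07 to −0.01, −0.05 to 0.03, −0.05 to 0.01 and 0.01 to 0.06 with 1 library left out. The integrated stress and unfolded protein response list had 10 members higher and 20 lower with a median of −0.03 (adjusted p = 0.647), or −0.09 to 0.02 with 1 library left out. Its most abundant members were the endoplasmic reticulum chaperone genes HSP90B1, at 478 ± 60 and 417 ± 13 CPM, and HSPA5, at 376 ± 41 and 445 ± 117 CPM.

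Glycolysis and hypoxia response genes were lower in 23 of 30 tested members, with a median log2 fold change of −0.11. The camera adjusted p was 0.0589, and it was 0.0369 with the replicate number as a block and 0.950 with the estimated correlation of 0.147. With the preset correlation and no block it was 0.0398, 0.0362 and 0.499 without control replicate 1, 2 and 3 in turn (medians −0.12, −0.10 and −0.05), and 0.195, 0.533 and 0.0472 without FABP4 si267 replicate 1, 2 and 3 in turn (medians −0.14, −0.09 and −0.14). PKM, the pyruvate kinase of glycolysis, measured 8999 ± 615 and 8554 ± 773 CPM in control and FABP4 si267 libraries, and GAPDH 4280 ± 333 and 3774 ± 249 CPM (log2 fold change −0.18, 95% confidence interval −0.42 to 0.06).

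No shift of proliferation genes was called. In the list of DNA replication and the G1/S transition, 24 of 36 members were higher, with a median of 0.07 (camera adjusted p = 0.2995). MCM7 and MCM4, subunits of the replicative helicase, gave 724 ± 95 against 796 ± 56 CPM and 647 ± 91 against 783 ± 129 CPM. In the mitosis and G2/M list 26 of 35 members were lower, with a median of −0.08 (adjusted p = 0.188). CDC20, an activator of the anaphase-promoting complex, stood at 394 ± 13 and 358 ± 37 CPM, and FOXM1, a transcription factor of the G2/M programme, at 371 ± 12 and 357 ± 31 CPM. Of the p53 targets and cell cycle inhibitors 17 were higher and 10 lower, with a median of 0.04 (adjusted p = 0.565). CDKN1A, which encodes the inhibitor p21, gave 1075 ± 185 and 1135 ± 183 CPM, and CDKN2A 349 ± 19 and 334 ± 26 CPM. When 1 library was left out, the median ranged from 0.04 to 0.09 for replication, −0.12 to −0.07 for mitosis and −0.04 to 0.11 for p53 targets.

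Interferon stimulated genes formed the other list that passed with the preset correlation. Of 33 tested members 27 were lower and 6 higher in FABP4 si267 cells, with a median log2 fold change of −0.19 (camera with a preset correlation of 0.01, adjusted p = 0.00341). The correlation estimated for this list was 0.148. The call was lost with that estimate (camera adjusted p = 0.950) and with fry (adjusted p = 0.704). Summed over the list, expression was 626 ± 35 CPM in control and 574 ± 23 CPM in FABP4 si267 libraries. STAT2, a transcription factor of the interferon response, measured 79.6 ± 10.0 and 82.0 ± 5.4 CPM, and EIF2AK2, the kinase activated by double-stranded RNA, 66.8 ± 9.9 and 58.7 ± 5.5 CPM. The interferon list's call was also lost without control replicate 2 (adjusted p = 0.0610), where the median was −0.09, and without control replicate 3 (0.205), where it was −0.18. Inflammation and NF-kB targets had 7 members higher and 15 lower with a median of −0.10 (adjusted p = 0.565). With 1 library left out the median ranged from −0.22 without FABP4 si267 replicate 3 (adjusted p = 0.0274) to 0.01 without control replicate 3 (0.866), and with the stricter filter it was −0.01 (0.769). NFKB2 and NFKBIA, a subunit and an inhibitor of NF-kB, stood at 347 ± 38 against 332 ± 23 CPM and at 111 ± 16 against 110 ± 12 CPM.

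**Figure D3:**
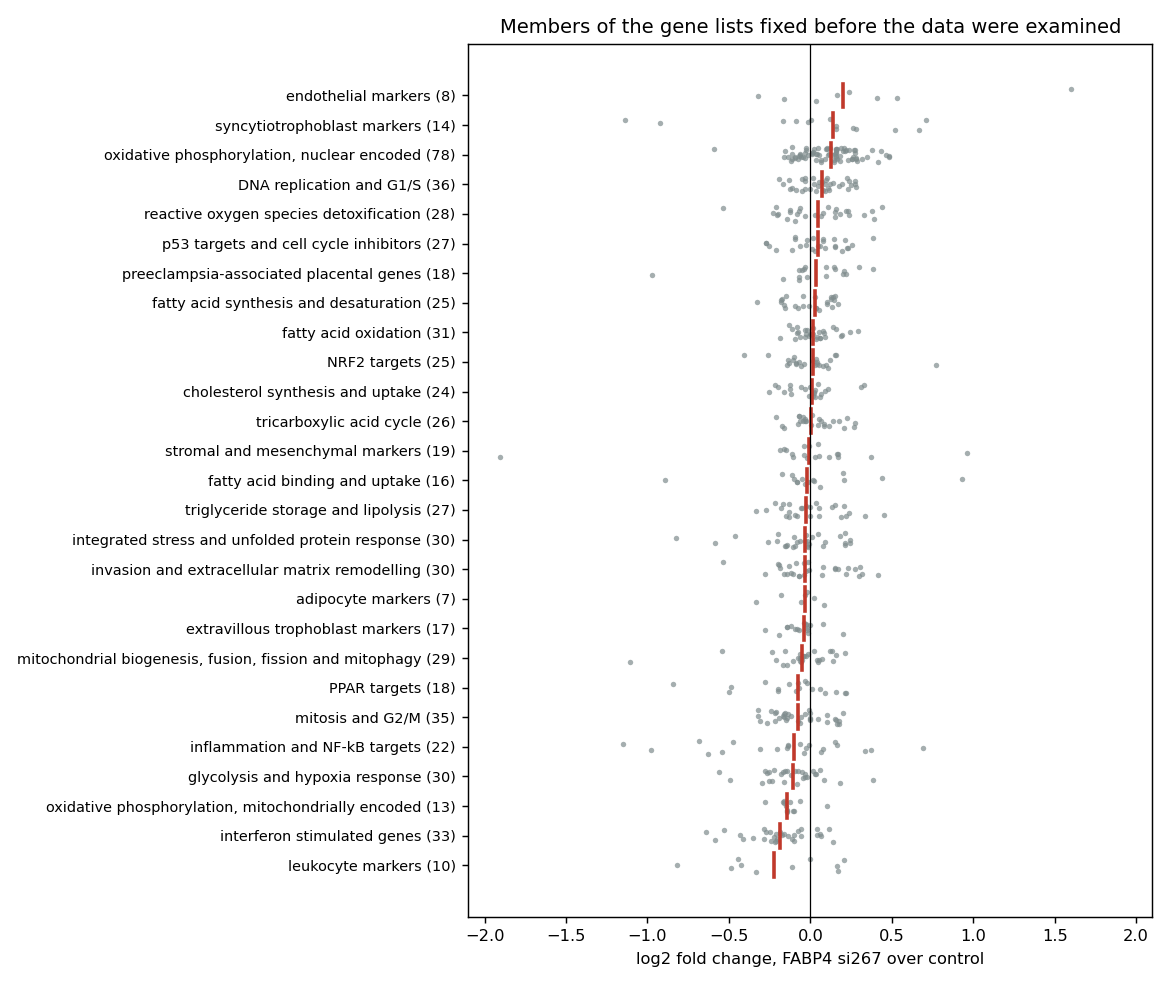
Log2 fold changes, FABP4 si267 over control (horizontal axis), of the tested members of the 27 gene lists (vertical axis, number of tested members in parentheses). Each point is 1 gene, with random vertical scatter, and the red bar is the list's median. Medians lie between −0.22 and 0.20, with 0.13 for nuclear encoded oxidative phosphorylation and −0.19 for interferon stimulated genes.

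No shift was called for genes of trophoblast identity and invasion. Extravillous trophoblast markers had 2 members higher and 15 lower with a median of −0.04 (camera adjusted p = 0.565). The median with 1 library left out ranged from −0.14 without control replicate 2 (adjusted p = 0.0924) to −0.01 without FABP4 si267 replicate 2 (0.988). The keratin genes KRT8 and KRT18 stood at 1723 ± 22 against 1506 ± 161 CPM and at 927 ± 83 against 876 ± 55 CPM, whereas HLA-G, a marker of extravillous trophoblast, was at 0 in all 6 libraries. Of the invasion and extracellular matrix remodelling list 12 members were higher and 18 lower, with a median of −0.03 and a mean of 0.01 (adjusted p = 0.944). VIM and FN1, which encode vimentin and fibronectin, measured 1392 ± 116 against 1386 ± 147 CPM and 342 ± 29 against 339 ± 26 CPM. Preeclampsia-associated placental genes had 9 members higher and 9 lower with a median of 0.03 (adjusted p = 0.565). NDRG1 and ENG, a hypoxia-responsive gene and the gene of endoglin, gave 205 ± 35 against 199.8 ± 20.0 CPM and 170.2 ± 25.1 against 166 ± 7.8 CPM, while LEP, CRH and SIGLEC6 were at 0 in all 6 libraries. Medians with 1 library left out ranged from −0.08 to 0.05 for invasion and from 0.02 to 0.12 for the preeclampsia list, which had −0.01 with the stricter filter.

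Markers of other cell types were examined as a check, and no shift was called for any of these lists. Syncytiotrophoblast markers had 9 members higher and 5 lower with a median of 0.14 (camera adjusted p = 0.565). It was 0.02 without control replicate 2, 0.20 without FABP4 si267 replicate 3 and 0.01 with the stricter filter. The most abundant were the amino acid transporter gene SLC1A5, at 569 ± 91 and 535 ± 47 CPM, and the syndecan gene SDC1, at 241 ± 42 and 292 ± 13 CPM. Stromal and mesenchymal markers had 9 higher and 10 lower with a median of −0.01 (adjusted p = 0.944), or −0.06 to 0.05 with 1 library left out, and COL6A2, a collagen VI chain, gave 1241 ± 191 and 1222 ± 25 CPM. Of the endothelial markers 6 were higher and 2 lower, with a median of 0.20 (adjusted p = 0.327). With 1 library left out the adjusted p ranged from 0.0165 without FABP4 si267 replicate 3 (median 0.36) to 0.659 without FABP4 si267 replicate 1 (median 0.15). Among them EGFL7 stood at 109 ± 19 and 97.6 ± 1.5 CPM and ECSCR at 6.07 ± 0.55 and 6.80 ± 1.85 CPM. Leukocyte markers had 3 higher and 7 lower with a median of −0.22 (adjusted p = 0.565), which was 0.31 without control replicate 3, −0.38 without control replicate 2 and 0.02 for counts divided by 4. The most abundant were CD68, at 9.60 ± 3.09 and 10.8 ± 4.6 CPM, and ITGAX, at 1.96 ± 0.72 and 2.19 ± 0.61 CPM. Adipocyte markers had 2 higher and 5 lower with a median of −0.03 (adjusted p = 0.885), or −0.15 to 0.00 with 1 library left out, with CEBPA at 29.5 ± 3.2 and 31.2 ± 2.6 CPM and LIPE, the hormone-sensitive lipase gene, at 19.7 ± 1.1 and 18.9 ± 2.1 CPM.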

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

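The test on counts divided by 4 and rounded was chosen only after the data were seen. Of 19513 genes tested, 0 were called in the edgeR quasi-likelihood test, against 6 (4 rising, 2 falling) with DESeq2, and 565 had an unadjusted p under 0.05. The count of changed genes was also 0 with RLE size factors, library size only, limma-voom, no filter, the stricter filter, divided counts, a 2-fold minimum and an adjusted p under 0.01. With the replicate block it was 1 (0 rising, 1 falling), and besides the 2 lists it added the block changed no other call. Leaving out 1 library gave between 0 and 5 changed genes, 0 to 5 rising and 0 to 2 falling. The number of genes at an unadjusted p under 0.05 was 818 with the replicate block, 880 without a filter and 285 with the stricter filter, which tests fewer genes. It ranged from 461 to 1202 with 1 library left out. The number of gene lists called, 2 as reported, was 4 with library size only, with the stricter filter, with the replicate block and with divided counts, in each case by adding mitochondrially encoded oxidative phosphorylation and glycolysis. The stricter filter left the endothelial, leukocyte and adipocyte lists untested, so its adjustment covered fewer lists. The number of lists called was 0 with an estimated correlation, 0 with fry, and 1 to 5 with 1 library left out. For nuclear oxidative phosphorylation the adjusted p was 0.950 with an estimated correlation, 0.883 with fry and from 0.00224 to 0.675 with 1 library left out. For interferon stimulated genes it was 0.950, 0.704 and from 7.4e-06 to 0.205. Leaving out 1 library turned the sign of the median in 13 of the 27 lists, 0 of them among the 2 called. Apart from the estimated correlation, which widens the test for lists whose genes vary together, the cause of these moves was not tested. The tested genes named in the text with a level or fold change gave 75 results, counting each identifier of a shared symbol, and 1039 values under an alternative. Of these, 1031 stayed short of the threshold and 0 reversed, where a sign change counted only if both log2 fold changes exceeded their SE. The other 8 passed with the sign they had, namely ENSG00000255439, IP6K3, ORAI1 and CD99 with DESeq2, CD99 with the replicate block, ENSG00000255439 without FABP4 si267 replicate 2, CORO7-PAM16 without control replicate 1 and ADORA2A without control replicate 2. Depth limits genes near the floor of 12 counts, and 3 replicates with this spread recovered few simulated changes of 1.5-fold in genes with a mean of at least 5 CPM.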

Other observations

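The test of 1 library setting the respiratory chain difference and the sums over shared loci were chosen only after the results were seen, and the immediate early gene pattern was noticed in these data.

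EGR1, FOS and FOSB, immediate early genes that respond within minutes to growth factors, serum or handling, had lower means in the FABP4 si267 libraries, though none passed the test. EGR1 stood at 494 ± 169 CPM in control and 248 ± 70 CPM in FABP4 si267 libraries (log2 fold change −0.99, SE 0.24), FOS at 440 ± 222 and 196 ± 58 CPM (−1.17, SE 0.31) and FOSB at 20.3 ± 18.7 and 4.77 ± 1.05 CPM (−2.09, SE 0.52), each with an adjusted p of 1.00 in edgeR's quasi-likelihood test. A hypothesis that the difference is shared by the class was tested on other immediate early genes, listed before their values were seen. Of 42 tested, 32 were lower, with a median log2 fold change of −0.17 (−0.16808, camera p = 0.00136 with a preset correlation and p = 0.391 with an estimated correlation). CCN2 stood at 154 ± 34 and 95.5 ± 28.9 CPM, NR4A1 at 31.8 ± 10.5 and 20.9 ± 1.0 CPM, and JUN at 845 ± 210 and 618 ± 96 CPM, while BTG2, at 48.2 ± 5.9 and 62.9 ± 7.2 CPM, was among the 10 that were higher. Control replicate 3 held the highest level of EGR1, FOS and FOSB, at 679.9, 668 and 41.3 CPM. Without that library the median over the other genes was −0.06856 (camera with the preset correlation, p = 0.494). With the same preset correlation it was −0.13 (p = 0.0550) without FABP4 si267 replicate 1, −0.15 (p = 0.0646) without replicate 2 and −0.28 (p = 4.12e-06) without replicate 3 of that group, −0.27 (p = 2.8e-04) without control replicate 1 and −0.20 (p = 3.31e-05) without control replicate 2. With the preset correlation and the replicate block it was −0.16 (p = 3.71e-05). A lower level, if the class shares it, may belong to the cells given si267 or to how 1 control culture was handled, and the data leave both open.

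FABP4 was at 0 in all 6 libraries. Reads dropped or passed to a near-identical copy were weighed as an explanation, and the sequence argued against it for copies in GENCODE 29. Of the 1463 75-base words of its annotated transcripts, 100% occur in no GENCODE 29 transcript of another gene (83.2% for FABP5). Identifiers of the deposited table that are not in GENCODE 29 were not searched. A copy among them, a level below the floor of 12 counts in these cultures and an omission in the counting stay open, and none was tested. No effect on the target RNA can be read from these libraries.

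Of 78 nuclear respiratory chain genes, 57 had a higher and 21 a lower mean in the FABP4 si267 libraries, with a median log2 fold change of 0.13 and no member past the test. The list's call was lost with an estimated correlation (adjusted p = 0.950). A trend with the length of each gene's longest transcript was weighed, because the list's median length was 1510.5 bases against 2975 over all tested genes. After its removal the median was 0.1102 (95% bootstrap interval over genes 0.056 to 0.144), which argues against that length as the whole cause. Removal of a GC trend left 0.1118 (0.057 to 0.153). Both intervals resample the genes, which vary together, and not the libraries, so they do not bound the difference between the groups. Without FABP4 si267 replicate 2 the median was 0.04591, so the difference may largely reflect that library. An effect of si267 stays open and was not tested further.

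Several of the larger log2 fold changes belonged to genes that overlap another gene, form part of a readthrough gene or share their symbol with another identifier. Of 63 genes with an unadjusted p under 0.01 and at least a 2-fold change, 56 were in GENCODE 29. Of these, 24 overlapped another gene on the same strand, against 6024 of the 18407 other tested genes in GENCODE 29 (odds ratio 1.542, two-sided Fisher exact p = 0.117). The odds ratio was 2.20 for protein-coding genes (Fisher exact p = 0.0277) and 0.743 for those with a mean of at least 5 CPM (Fisher exact p = 0.761, 3 of 11 genes overlapping). Over these genes as a set, counts traded between overlapping genes and changes of the genes themselves cannot be told apart. The odds ratios lie on both sides of 1, and the test over all these genes missed the threshold. That test does not cover the second CD99 identifier, ENSG00000292348, which is not in GENCODE 29. It was higher in the FABP4 si267 libraries (log2 fold change 0.52, SE 0.12) where ENSG00000002586 was lower. With a sum of 251.99 ± 20.0 against 247.37 ± 7.6 CPM, this argues against a fall of CD99 as a whole. Sums were taken over a readthrough gene with its parts, or, for CD99, WASH2P and CD99P1, over the identifiers that share the symbol. Log2 ratios of the sums were −0.03 for CD99 (−1.25 for ENSG00000002586 alone), −0.07 for CORO7-PAM16 (−3.34 alone), −0.07 for SPECC1L-ADORA2A (−3.76 for ADORA2A alone), −0.04 for WASH2P (1.18 alone), −0.15 for ZNF559-ZNF177 (−1.55 alone), 0.16 for SENP3-EIF4A1 (2.04 alone) and 0.47 for CD99P1 (1.76 alone), whose sum went from 3.03 ± 0.46 to 4.19 ± 1.05 CPM. In control libraries ADORA2A held 5.07 of the 71.1 CPM of its locus, CORO7-PAM16 8.86 of 97.1 and ZNF559-ZNF177 4.67 of 21.5. Sums over the loci of ADORA2A, CORO7-PAM16 and ZNF559-ZNF177 would move little whether or not counts were traded, so they do not decide the question. WASH2P went from 5.83 to 13.2 CPM, while its sum went from 31.5 ± 2.8 to 30.5 ± 0.70 CPM. SENP3-EIF4A1 went from 77.6 to 320 CPM, and its sum from 1103 ± 151 to 1234 ± 22 CPM. Without control replicate 2, edgeR's quasi-likelihood test called ADORA2A lower (log2 fold change −4.32) and the readthrough gene SPECC1L-ADORA2A higher (12.3) in the FABP4 si267 libraries. These 7 sums and the opposite calls at the ADORA2A locus were chosen after their values were seen.

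The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The labelled split gave 0 changed genes and the highest of the others 7. For genes at an unadjusted p under 0.05 the labelled split gave 565 and the highest of the others 2474, for control replicates 1 and 3 with FABP4 si267 replicate 1 against the rest, and 6 of the 10 splits gave at least 565. The count of 2474 is several times the labelled one, but as the highest of the splits it was not tested against chance. This split follows the first principal component, negative for these 3 libraries and positive for the rest. The same 3 libraries held the highest shares of mitochondrially encoded counts, 4.34, 4.46 and 4.15%, against 4.01, 3.55 and 3.82% in control replicate 2 and FABP4 si267 replicates 2 and 3. Splits that part all 3 same-numbered pairs, as the labelled one does, gave 374, 282 and 682 genes, and those that part 1 pair gave 470 to 2474.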
